A study of Trichophyton rubrum with 6 samples.

How the data were processed

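Messenger RNA was measured by sequencing in 6 cultures of the fungus Trichophyton rubrum, strain STRB12, 3 grown with Huangqin Decoction (HQD) and 3 grown without it. Per the labels' protocols, poly(A) RNA was enriched with oligo(dT) beads, fragmented, copied to cDNA with random hexamers and sequenced as paired reads on a DNBSEQ-T7 instrument. No label gives a strand-specific step, so reads of overlapping genes on opposite strands could not be separated here.

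The deposited count table holds whole-number estimated counts per gene, and the deposited FPKM table holds the same 8843 genes. Per the submitters' processing notes, Bowtie2 2.2.5, StringTie 2.1.2 and DESeq2 1.4.5 were used by the authors. The role of each tool, the genome build, the annotation version and the counting mode were not given in the sources used here. In the 1892 genes with at least 2000 counts in every library, the ratio of count to FPKM varied across libraries with a median SD of 0.00763%, after 1 factor per library was taken out. In the 104 genes with 10 to 49 counts in every library that SD was 1.59%, the size that rounding to whole numbers leaves. The counts and the FPKM were therefore treated as 2 forms of one estimate, not as independent measurements. Whether the mates of a pair were counted once or separately was not given, so the counts may overstate the number of independent fragments. The counts were used as deposited, without further rounding.

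Of the 8843 identifiers, 8616 were TERG locus tags and 227 were MSTRG loci, the form in which StringTie names assembled loci outside an annotation. All 8616 tags occurred in the RefSeq gene table of assembly ASM15142v1, which gave 0 of them a symbol other than the tag and 0 a synonym. Neither the deposited tables nor that table pairs the tags with gene or product names. For this reason the 32 gene lists that had been fixed as search words on product names (among them the glyoxylate cycle, the tricarboxylic acid cycle, glycolysis, the respiratory chain, ergosterol synthesis, the cell wall, peptidases, transporters, ribosomal proteins and spore markers) matched 0 genes. They were not tested, and the camera test planned for them was not run. Coordinates are not printed, because the build behind the counts was not given; the reference table was used only for gene order and gene length.

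Genes with low counts were removed with edgeR's filterByExpr, which left 8733 genes and removed 110. HQD was compared with control over all 6 libraries with edgeR 4.0.16 (R 4.3.3): TMM factors, estimateDisp and glmQLFit with robust moderation, and the quasi-likelihood test, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p. The standard error (SE) of a log2 fold change was taken as the fold change divided by the square root of its F statistic, and is approximate. CPM are taken over the TMM-scaled library total. No covariate was used. The test was run on simulated counts for the 8733 genes with the means, library sizes and gene-wise dispersions of these libraries, in which 200 genes were changed by known folds, 50 for each size. In that simulation of HQD against control, edgeR recovered 4% of the genes changed 2-fold, 76% of those changed 4-fold and 100% of those changed 8-fold. DESeq2 recovered 24%, 88% and 100% of them, with 36 false calls among 191, against 10 false calls among 149 for edgeR. Genes were drawn independently at the estimated dispersions, so the simulation may overstate recovery in the real libraries.

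Alternatives were DESeq2's size factors, upper quartile factors or library totals in place of TMM, DESeq2 1.42.0 or limma-voom (limma 3.58.1) in place of edgeR, no filter or a filter of at least 50 counts in every library of a group, the replicate number as a block, limma on log2(FPKM + 1) or log2(FPKM + 0.1) of genes with a mean FPKM of at least 1, the same without that filter, a fold threshold of 1.5 inside the test, an adjusted p under 0.01, and leaving out each library in turn. The comparison, its test, these alternatives, the rule for named genes and the runs of neighbouring genes were fixed before the data were examined. The legacy form of the quasi-likelihood fit, the fit without robust moderation, runs made from DESeq2 calls or from unadjusted p-values, DESeq2 without each library, the levels of the runs without each library and the counts of runs in other splits were added after seeing the data. The replicate numbers of the 2 groups coincide, but no label says that a number marks a shared culture or day. The deviations of same-numbered libraries from their group means correlated at -0.006, -0.017 and -0.26, so the numbers were not treated as pairs.

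By the rule fixed for named genes, when no product names can be had, the 2 highest and 2 lowest fold changes are named among genes that passed, had an average log2 CPM of at least 2 and had no overlap between the 3 HQD and the 3 control values. Runs of neighbouring genes were counted along the order of the 8514 tested genes of the reference table, in which the 19 stretches of gene order are parted where the coordinates start again, and set against 10000 permutations of the calls, which treat neighbours as independent. They were also counted in the 9 other splits of the libraries, among the genes with the smallest p, as many as the real split had called. Correlations of fold changes between neighbours were set against 1000 permutations. These steps and the exact tests used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. All 6 columns of both tables were used, and 0 columns were left out.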

Results

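RNA sequencing was performed in Trichophyton rubrum STRB12 to find the genes whose transcripts differ when the fungus grows with Huangqin Decoction. T. rubrum is a dermatophyte, a fungus that infects skin and nails, and HQD is a traditional Chinese herbal formula. HQD was given at 3.13 mg/mL, which the labels name as the minimum inhibitory concentration. The control cultures received the same volume of medium. Mycelium was harvested after 5 days at 28 °C. Each group held 3 libraries, which the labels call biological replicates. Total counts ranged from 32328626 to 33894552 in the control libraries and from 29549777 to 34963711 in the HQD libraries. Between 8811 and 8825 of the 8843 genes had a count above 0 in each library. A check for a library deposited more than once found none, since the counts of every pair differed by more than counting noise.

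The groups did not overlap on the first principal component of expression, but libraries within a group differed widely. A single HQD culture stood apart from the other 5 libraries. Each of the 6 libraries had its highest Spearman correlation across genes with a library of its own group. Still, HQD replicates 2 and 3 correlated at 0.917 and 0.913 with HQD replicate 1, below their 0.925 to 0.949 with the controls. Control replicate 1 correlated at 0.927 with control replicate 2, below its 0.938 and 0.949 with HQD replicates 2 and 3. HQD replicate 1 had a mean Spearman correlation across genes of 0.901 with the other libraries, whereas the remaining 5 had means from 0.928 to 0.942. On the first principal component of log2 CPM, with 38.8% of the variance, HQD replicate 1 lay at -67.4. The other HQD libraries lay at -10.4 and 4.87 on it, and the controls between 12.5 and 38.8. On the second component, with 24.2%, HQD replicates 2 and 3 lay at -35.4 and -27.5, control replicate 1 at -14.6, and the others between 23.8 and 28.8. HQD replicate 1 had 223 genes that were over 4-fold lower than in both other HQD libraries and 34 that were over 4-fold higher. In the other 5 libraries, between 1 and 44 genes were that much lower than in both others of their group, and between 2 and 65 were that much higher. The edgeR common dispersion was 0.145, which is a biological coefficient of variation of 0.38.

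**Figure D1:**
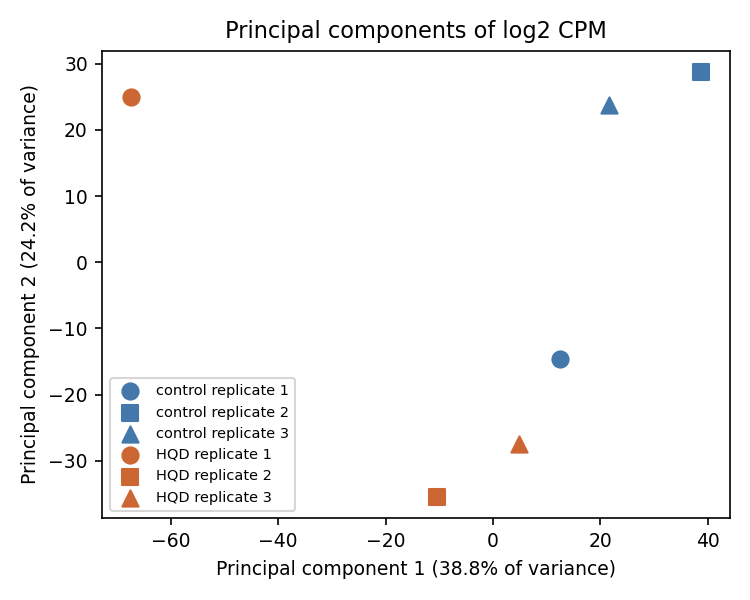
Scores of the 6 libraries on the first (x axis, 38.8% of the variance) and second (y axis, 24.2%) principal components of log2 CPM; blue points are control and orange points HQD libraries, with a marker shape per replicate. HQD replicate 1 lies alone at -67.4 on the first component, and control replicate 1 lies between the other controls and HQD replicates 2 and 3 on the second.

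The first question was which single genes changed with HQD. In the edgeR quasi-likelihood test 7 genes rose and 0 fell, and all 7 rose by at least 2-fold. Their fold changes ran from 5.53 to 18.6, with a median of 8.95, and each had an adjusted p of 0.0239. In every one of the 7, each HQD library lay above each control library. Their mean levels ran from 0.463 to 128 CPM in the controls and from 8.68 to 799.6 CPM with HQD. The tables give locus tags without gene names, so what these genes encode is not stated here. The largest rise among the 7 was that of TERG_00175, from 0.463 ± 0.142 CPM (SD, n = 3) in control to 8.68 ± 4.25 CPM (SD, n = 3) with HQD, a log2 fold change of 4.21 with an SE of 0.499. It was a low-level transcript, at a mean of 0.52 FPKM in control and 9.86 FPKM with HQD. The next largest was that of TERG_08321, from 31.2 ± 11.4 CPM (SD, n = 3) to 437.3 ± 129.6 CPM (SD, n = 3), a log2 fold change of 3.81 with an SE of 0.423. In HQD replicate 1, the library that stood apart, TERG_00175 was at 13.2 CPM and TERG_08321 at 288.1 CPM, above all controls in both cases.

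The 7 calls depended on which libraries entered the fit. Without control replicate 1 edgeR called 3 genes, all lower with HQD and 0 of them among the 7. Without control replicate 2 or control replicate 3 it called 0 genes, with 897 and 712 genes at an unadjusted p under 0.05. Without HQD replicate 1 it called 24 genes, all higher and including the 7. Without HQD replicate 2 it called 3, with 2 higher and 1 lower, of which 2 were among the 7. Without HQD replicate 3 it called 8, of which 6 were among the 7. Across these fits the log2 fold change of TERG_00175 stayed between 3.75 and 4.50 and that of TERG_08321 between 3.54 and 4.02, while their adjusted p-values reached 0.294 and 0.26.

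A wider set of genes was called in both directions when DESeq2, the tool that the submitters' processing notes name, was run on the same counts. At an adjusted p under 0.05 it called 347 genes, of which 203 rose and 144 fell, and 334 of them changed at least 2-fold. All 7 genes of the edgeR test were among them. The HQD and control values did not overlap in 309 of the 347, and 344 had an unadjusted p under 0.05 in edgeR. Both follow largely from choosing the genes by this contrast in these counts, and so are not independent support. In other splits of the libraries into 3 and 3, DESeq2 called at most 84 genes. Those splits put HQD and control libraries together in both groups, so an effect of HQD would widen their spread and lower that number. Without control replicate 3 DESeq2 called 120 genes, without control replicate 2 it called 181, and without HQD replicate 1 it called 486, of which 275 were among the 347. In edgeR, 1225 of 8733 genes had an unadjusted p under 0.05, of which 650 were higher and 575 lower with HQD. Independent genes would give 437 by chance, and the 9 other splits of these libraries into 3 and 3 gave from 105 to 819. The smallest adjusted p of a gene that was lower with HQD was 0.128 in edgeR. Regardless of the test, 846 genes were higher and 847 lower in all 3 HQD libraries than in any control, together 19.4% of the genes. A single gene would do so by chance in 10% of cases. Because genes vary together, the share in any 1 split may lie far from 10%, and it was not computed for the other splits. The median log2 fold change of all tested genes was 0.02 with TMM factors. At a median SE of 0.35 on the log2 scale (over genes with an absolute log2 fold change above 0.1), and with 4% of simulated 2-fold changes recovered, a change of 2-fold was mostly not detectable in these 6 libraries. Larger changes could be missed too, despite their high recovery in the simulation. A run of 5 genes with log2 fold changes from 3.05 to 4.37 (below) had a smallest adjusted p of 0.128 in edgeR.

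**Figure D2:**
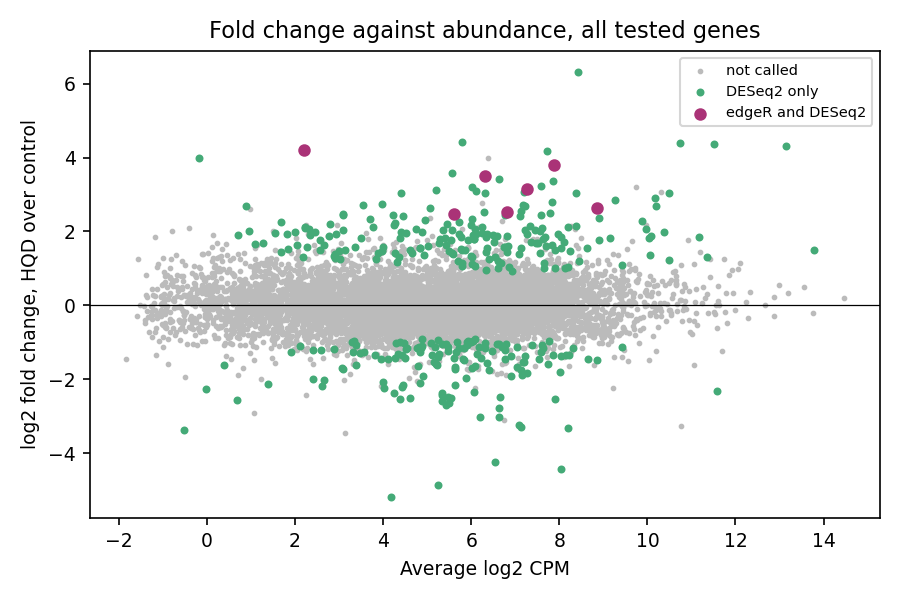
Log2 fold change of HQD over control (y axis) against average log2 CPM (x axis) for the 8733 tested genes; grey genes passed neither test, green genes passed in DESeq2 only, and purple genes passed in edgeR and DESeq2. The 7 purple genes all lie above 0, and the green genes lie on both sides.

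Of the 227 MSTRG loci, 219 were tested and 0 passed in edgeR. An unadjusted p under 0.05 was found in 22 of the 219, a smaller share than the 1225 of all 8733 tested genes. Of the 22, 17 were higher with HQD, and of the 1225, 650 were. This imbalance was not tested. DESeq2 called 8 of the 227 MSTRG loci, 5 higher and 3 lower, a share similar to its 347 of all 8843 genes. Together the MSTRG loci held 0.425% to 0.505% of the counts in the controls and 0.476% to 0.758% with HQD, ranges that overlap.

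Genes of some pathways lie side by side in fungal genomes, so runs of neighbouring genes changed in the same direction were sought. Among the 7 genes of the edgeR test there were 0 runs of at least 4 neighbours, and 0 of at least 3. With only 7 calls this was nearly certain, since their permutations over the gene order also gave at most 0 runs, so it says little. TERG_08321 had a neighbour that was 3.42 higher on the log2 scale but did not pass, with an adjusted p of 0.0686 in edgeR. Among the DESeq2 calls there were 3 runs of at least 4 genes, with 15 genes in all. When the 337 ordered genes with the smallest DESeq2 p were taken in each of the 9 other splits of the libraries, they formed from 0 to 4 such runs, and 2 of these splits had at least 3. Permuting the calls over the gene order gave at most 1 run, but this treats neighbours as independent, and adjacent genes also varied together within each group (0.216 to 0.29, below). The runs are named here by their first gene and were singled out after their values were seen. No gene in them passed in edgeR, where their smallest adjusted p was 0.128.

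The largest of these in expression was a run of 5 genes from TERG_02841. Its summed level was 1280 ± 1008 CPM (SD, n = 3) in control and 24096 ± 15729 CPM (SD, n = 3) with HQD, a ratio of 18.8. The ratio was 30.6 without control replicate 3 and 12.5 without HQD replicate 2. The 5 genes made up 2.3%, 4.03% and 0.893% of all scaled counts in HQD replicates 1, 2 and 3. Log2 fold changes of its members ran from 3.05 to 4.37, and in 4 of the 5 every HQD library lay above every control. A run of 4 genes from TERG_08709 was lower, at 602.6 ± 160.1 CPM (SD, n = 3) in control and 130.8 ± 92.8 CPM (SD, n = 3) with HQD, and every HQD library lay below every control in all 4 genes. It was 4.61-fold lower with all libraries and 7.8-fold lower without HQD replicate 2, which lay at 237.9 CPM against 81.2 and 73.3 CPM in the other 2. A run of 6 genes from TERG_06048 was at 423.6 ± 332.7 CPM (SD, n = 3) in control and 51.7 ± 12.2 CPM (SD, n = 3) with HQD. In this run control replicate 1, at 56.9 CPM, lay within the range of the HQD libraries, and the run was 8.2-fold lower with all libraries and 5.46-fold lower without control replicate 2. An exact two-sided permutation test of the log2 of the summed levels gave p = 0.1, 0.1 and 0.2 for the 3 runs in this order. The smallest p that 3 libraries against 3 allow is 0.1. As the runs were picked from calls on this same contrast, these p-values add no independent support.

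**Figure D3:**
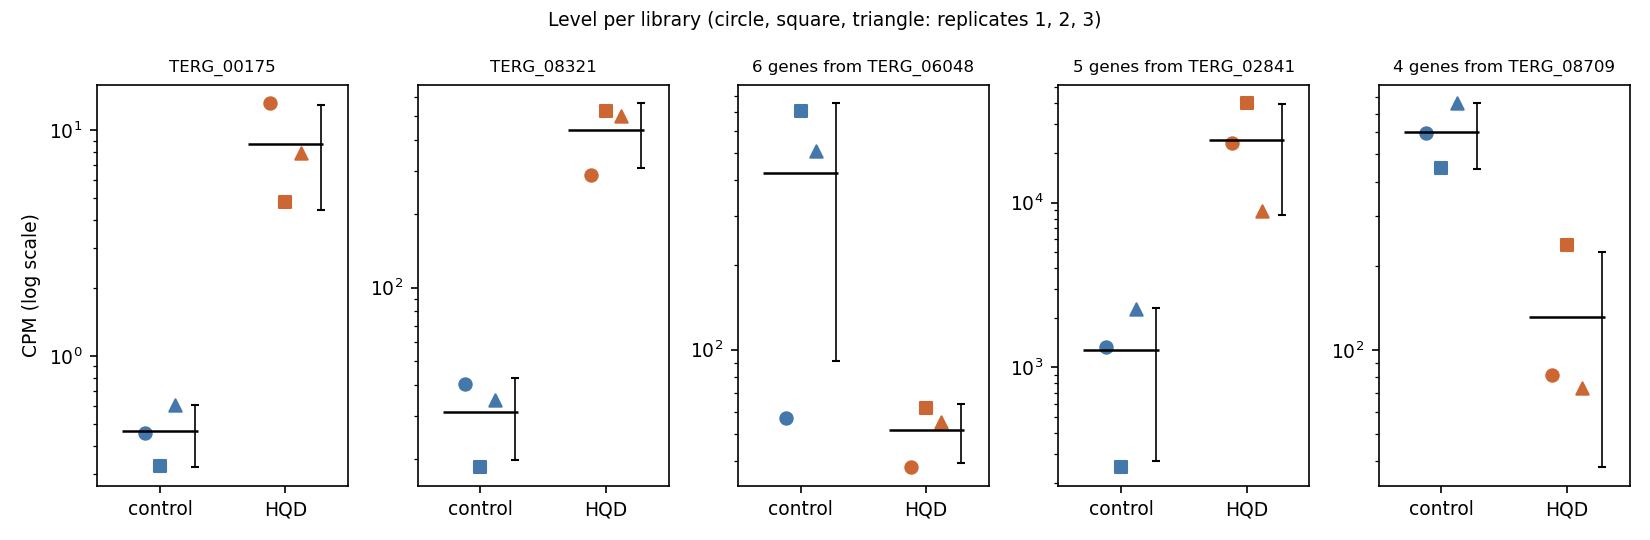
Level per library in CPM on log-scaled y axes for the 2 named genes and for the summed CPM of the 3 runs of neighbouring genes; symbols give the replicate number, horizontal bars the mean of 3 libraries and error bars the SD. TERG_00175, TERG_08321 and the run from TERG_02841 are higher in all HQD libraries, the run from TERG_08709 is lower in all of them, and in the run from TERG_06048 control replicate 1 lies among the HQD libraries.

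Gene order was taken from the reference assembly, and whether STRB12 keeps it was not checked. Across the 8514 tested genes in that order, the fold changes of adjacent genes correlated at a Spearman rho of 0.21 (8495 pairs). At most 0.0316 was reached in 1000 permutations of the gene order (permutation p = 0.001, one-sided, the smallest they can give). The value of 0.21 is a correlation across genes, which are not independent replicates. It was 0.152 for the 2493 adjacent pairs at least 1000 bp apart and 0.0733 for genes 2 places apart. At 10 places apart it was -0.00028. A correlation of similar size was present between libraries of one group. The deviation of each library from the others of its group correlated between adjacent genes at 0.216 to 0.29.

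**Figure D4:**
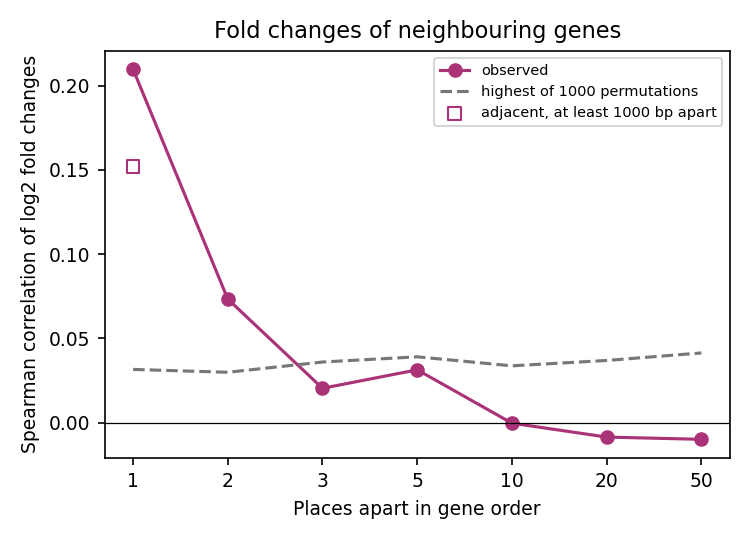
Spearman correlation of log2 fold changes (y axis) between genes a given number of places apart in gene order (x axis); filled circles are all pairs, the open square adjacent pairs at least 1000 bp apart, and the dashed line the highest of 1000 permutations. The correlation is 0.21 for adjacent genes and lies near 0 at 10 places.

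The title of the series names energy metabolism and the glyoxylate cycle, the pathway of isocitrate lyase and malate synthase that lets fungi build sugars from acetate and fatty acids. The tables used here give locus tags without product names, so the transcripts of this pathway and of the other gene lists were not analysed here.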

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

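The legacy and non-robust edgeR fits, the runs from DESeq2 calls or unadjusted p-values DESeq2 without each library and the run levels without each library were chosen after seeing the data. The 7 genes called by edgeR, all of them also changed at least 2-fold, became 12 with library totals in place of TMM factors, 347 in DESeq2 (334 at least 2-fold), 0 at an adjusted p under 0.01, and between 0 and 24 (the same for 2-fold changes) when single libraries were left out. With the replicate number as a block, edgeR called 0 genes, with 932 at an unadjusted p under 0.05. The numbers are not known to pair the libraries, no library correlated best with its own number (-0.006, -0.017 and -0.26 between same-numbered libraries), and the block also uses up residual degrees of freedom. In all, 12 settings for the count of genes, and 11 for 2-fold changes, stayed within 1.5 times, among them the fit without HQD replicate 3 (8 genes). All 7 genes were called again with DESeq2's size factors, upper quartile factors, limma-voom, both other filters and DESeq2, while limma on log2(FPKM + 1) shared 3 of its 7. Library totals moved the median log2 fold change of all genes from 0.02 to -0.11 and added 1 gene that fell. The fits on FPKM had medians from -0.11 to -0.13 and also called 1 gene that fell. TERG_00175 kept its direction in 19 settings, passed in 13 of them and missed in 6, with adjusted p-values up to 0.294. Its log2 fold change was 4.14 with the block (adjusted p = 0.0665) and 2.64 in limma on log2(FPKM + 1) (adjusted p = 0.0572), where the pseudocount shrinks the fold of a gene at this level, against 4.21 in edgeR. TERG_08321 passed in 14 and missed in 5, with log2 fold changes from 3.54 to 4.02 in the settings where it missed and adjusted p-values up to 0.26. The cause was not tested. The 0 runs of neighbouring genes became 3 with DESeq2 calls and 7 with genes at an unadjusted p under 0.05, and stayed 0 with other run lengths or 2-fold changes only. The tests of the gene lists and of the glyoxylate cycle genes were not run, since no gene names could be matched, and so their alternatives gave no values. At the depth of these libraries 110 genes had too few counts for the test, and 7 genes were called with or without them.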

Other observations

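The tests of a swapped library, of depth, of the scaling and of runs in other splits were chosen only after the results they bear on were seen. Genes at an unadjusted p under 0.05 in edgeR formed 7 runs of at least 4 neighbours changed in the same direction, 4 higher and 3 lower. The 1203 ordered genes with the smallest edgeR p formed from 7 to 14 such runs in each of the 9 other splits of the libraries, so the real split had no more runs than the others. Those splits took equally many genes whatever their p and still held the HQD libraries unevenly, so a part due to HQD is not excluded. Of the 7, 3 hold the runs of DESeq2 calls named above and 4 are others. The 4 are described here. Their genes were picked by an unadjusted p on this same contrast, so the gaps between groups are not independent support. One held 6 genes, and all 6 were higher in every HQD library than in any control, with a summed level of 399.9 ± 47.7 CPM (SD, n = 3) in control and 919.8 ± 379.7 CPM (SD, n = 3) with HQD. Another held 4 genes, all lower in every HQD library, at 1385 ± 283 CPM (SD, n = 3) in control and 722 ± 79.4 CPM (SD, n = 3) with HQD. One more held 4 genes, all higher in every HQD library, at 70.1 ± 13.3 CPM (SD, n = 3) in control and 130 ± 24.9 CPM (SD, n = 3) with HQD. The last held 4 genes, of which 2 were higher in every HQD library, at 793.9 ± 42.4 CPM (SD, n = 3) in control and 2477 ± 1668 CPM (SD, n = 3) with HQD, where the libraries lay at 4320.9, 1074 and 2035 CPM. None of the genes in these 4 runs passed in edgeR, where their smallest adjusted p-values were 0.128, 0.243, 0.214 and 0.247 in this order.

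Other splits of the 6 libraries into 3 and 3 were compared with the real one. The real split gave 7 edgeR calls, all at least 2-fold, and the highest of the other 9 gave 3. DESeq2 gave 347 calls in the real split and at most 84 in the others. In each case 1 of the 10 splits, the real one, gave a result as large. For runs of neighbours among equally many genes, the real split gave 3 by DESeq2 and the highest other gave 4, and by edgeR it gave 7 against 14, with as many in 3 and 10 of the 10 splits. Splits as few as 10 cannot give a share under 0.05. The other splits also mix HQD and control libraries in both groups, so an effect of HQD would lower their counts of called genes.

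HQD replicate 1 stood apart from the other libraries. The correlations argue against a swap with a control. HQD replicate 1 had its highest correlation with HQD replicate 2, and 0 of the 3 controls had theirs with an HQD library. On the second principal component, however, HQD replicate 1 lay at 25, with control replicates 2 and 3 at 28.8 and 23.8. Control replicate 1 lay at -14.6 there, nearer to HQD replicates 2 and 3. With HQD replicate 1 and control replicate 1 exchanged, DESeq2 called 84 genes. This was the most of the other splits, against 347 in the real one. A swap is therefore not excluded. Depth as the cause is argued against. Over the 4648 genes with a mean of at least 1000 counts, the mean correlation of HQD replicate 1 was 0.698, below the 0.78 to 0.826 of the other 5. A trend with gene length accounted for 4.28% of the variance of its deviation, against 0.713% to 2.95% in the other 5. That deviation correlated with gene length at 0.206, the furthest from 0 of the 6 libraries. The length trend was thus largest in this library but covered little of its deviation. A larger response of the same genes remains open. Over disjoint controls its change correlated across genes at 0.238 with that of the other HQD libraries, against 0.33 and 0.247 for replicates 2 and 3, and these ranges overlapped with the choice of control.

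All 7 genes that passed in edgeR rose. A scaling artefact that hid falling genes would show falls under another scaling, and across 4 scalings at most 1 gene fell, with library totals, while 7 to 11 rose, so the prediction of no falls under any scaling was missed by 1 gene and the test leaves scaling open. Without HQD replicate 1 edgeR called 24 genes, again with 0 falls, and without HQD replicate 2 it called 3, with 1 fall. Without control replicate 1 edgeR called 3, all falls, whereas DESeq2 on all libraries gave 203 higher and 144 lower. The size factors do not account for this difference between the tools, since edgeR with DESeq2's size factors called 7 genes higher and 0 lower. What else sets the tools apart in this split was not tested.

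Neighbouring genes had similar fold changes. Reads shared by adjacent genes are a possible cause. Against it, values above the permuted range were predicted at 1000 bp or more and at 2 and 3 places apart. Pairs at least 1000 bp apart still correlated at 0.152, above the highest permuted value of 0.0727. Genes 2 places apart correlated at 0.0733, above the highest permuted value of 0.0299. At 3 places apart the value of 0.0204 lay within the permuted range, so the prediction was missed and the test leaves shared reads open. The correlation was not particular to HQD, since 6 of the 10 splits of the libraries, the real one included, gave as high a value, up to 0.303. A candidate explanation is that stretches of the genome vary together between cultures whatever the treatment, and the runs named above may be part of that variation. Tandem gene copies that share reads were not tested, as no sequences were used here.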
